A study of Mus musculus with 4 samples.

How the data were processed

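Single-nucleus RNA sequencing data of mouse hippocampus were used, with 2 control libraries and 2 libraries labelled Ftl1 cKO. Per the labels, aged mice that carry an inducible Cas9 received a lentivirus with a Synapsin-driven Cre recombinase and either a non-targeting guide RNA or a guide RNA against Ftl1. Per the labels' protocols, nuclei of frozen hippocampi were sorted either as Hoechst-positive and NeuN-positive or as only Hoechst-positive, 10000 were loaded per library, and libraries were made with a droplet 3' kit. Which of these sorts was used for each library, the age of the animals and the site that the guide cuts are not given in the sources used here.

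The deposited values are UMI counts per gene and barcode, which were not normalized by the authors. Per the submitters' processing notes, bcl2fastq, Cell Ranger 7.1, R 4.2.2 and Seurat were used with the mouse build mm10. The file headers name other Cell Ranger releases than those notes, and whether intronic reads were counted is not stated. Each library came as a matrix of the barcodes that the authors called as nuclei and as a raw matrix with empty droplets. The matrices hold 22548 features, of which 22545 are mouse genes and 3 are vector sequences (CreWpre, gRNA3long and gRNAslong). Of the mouse gene IDs, 22404 (99.4%) are in GENCODE release M21, from which gene positions and spans on mm10 were taken.

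Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. Doublets were called in each library with Scrublet, as in scanpy 1.11.5, and removed; they made up 9.84% and 8.78% of the control nuclei and 5.37% and 10.0% of the nuclei of the libraries labelled Ftl1 cKO. The 48447 nuclei that were left came from 13608 and 14467 barcodes in the control libraries and from 12357 and 14671 in the libraries labelled Ftl1 cKO, all above the number loaded. Counts were log-normalized and scaled within each library, 2000 variable genes without mitochondrial and vector features were reduced to 40 principal components, and a graph of 15 neighbours was clustered by the Leiden method (leidenalg 0.10.2) at resolution 1. Of 32 clusters, 19 were named after 13 cell classes from marker lists fixed before the data were examined, and 13 clusters with 6255 nuclei stayed unnamed and outside the neuronal sum. Some unnamed clusters had neuronal levels of Snap25 and Rbfox3. The largest stood at 1331 and 339 CPM, against 838 and 457 in dentate granule-like and 369 and 39.8 in oligodendrocyte-like clusters. The term "all neuronal nuclei" therefore covers only nuclei of clusters named as a neuronal class. A cluster was named only where at least 3 markers of its class were raised by over 1 on the log2 scale, where no other class with at least 3 raised markers reached 60% of its mean marker fold, where markers of another class did not outnumber its own among the leading genes, and where under 50% of its nuclei were called doublets. A cluster of low depth also needed a marker of its class among its 10 leading genes. By this condition a cluster led by interferon-inducible genes stayed unnamed and outside the oligodendrocyte-like sums, although 10 oligodendrocyte markers were raised. Of its 130 nuclei, 116 came from control replicate 2. The fold and share limits of this naming were set after the clusters were seen; unnamed clusters held 11.3% and 14.2% of the control nuclei and 12.8% and 13.3% of the nuclei of the libraries labelled Ftl1 cKO. All names are "-like" names rebuilt from markers, and no annotation by the authors was used.

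Counts were summed per library and class, since nuclei are not replicates, and the sums were tested across the 4 libraries. The test was edgeR 4.0.16 (quasi-likelihood, robust, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05; the vector features stayed out of library sizes and tests. CPM stands for a count scaled to a fixed total (counts per 1e6), TMM-normalized where it stands beside a test and otherwise taken over all UMIs of the sum. Fold changes are the libraries labelled Ftl1 cKO over the controls, on the log2 scale with a standard error (SE). The difference of the effect between classes was tested as an interaction with library as a block, against dentate granule-like nuclei. The 18 functional and 18 marker gene lists were fixed before the data were examined and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, two-sided. At the preset correlation the p compares genes of a list with other genes and does not measure the spread between libraries. The estimated correlation rests on 2 against 2 libraries, and its power was not simulated. A list that does not pass with it is therefore not shown to be unchanged. Counts of members past the threshold are also given adjusted over the list alone. Class shares were compared with an exact two-sided permutation test over libraries, whose smallest possible p with 2 against 2 is 0.333. Shares of nuclei with a vector UMI are also given as the mean share that thinning gives, with each nucleus thinned to 800 UMIs, leaving out shallower nuclei. Intervals of single shares and counts are exact 95% intervals (Clopper-Pearson and Poisson) and cover counting error only.

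The genes named in the text follow a rule fixed before the data were examined. It takes Ftl1, Fth1 and Fh1. In all neuronal nuclei it takes the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean of at least 10 CPM in a group and with both libraries labelled Ftl1 cKO beyond both controls. In each of the 4 main neuronal classes it takes 5 in each direction by the same rule, and of each functional list up to 4 members with the smallest unadjusted p. Gene models without a name are counted only, and not every gene the rule takes is named. Other genes are said to have been chosen after their values were seen. Genes with near-identical copies, such as Ftl1, Fth1 and the ribosomal proteins with their pseudogenes, are uncertain where the counting could split reads.

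In simulated counts with the means, depths and dispersions of the neuronal sums, 200 of 15091 genes were changed. The edgeR test recovered 67.2% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 11 false calls. The simulated genes varied independently, with changes in both directions and no trend on gene span. The false calls therefore do not measure what a shift shared by many genes of a library would give. The depth was 54732885 and 56935694 UMIs over the kept nuclei of the control libraries and 52897107 and 67115740 over those of the libraries labelled Ftl1 cKO.

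Alternatives planned before the data were examined were DESeq2 1.42.0, RLE normalization, no filter on low counts, the replicate number as a block, each library left out, a stricter filter on nuclei (1000 genes, 1% mitochondrial UMIs), doublets kept, removal of 10% ambient RNA with the profile of barcodes of at most 100 UMIs, classes by each nucleus's own markers, matched numbers per class, all nuclei together and a clustering resolution of 0.5. Added after the data were examined were removal of a trend of fold on gene span (local regression, span 0.3), removal of ambient RNA at the largest share that glial markers, or glial and endothelial markers, allow, nuclei with or without a CreWpre UMI, the estimated correlation within each class, DESeq2 in the other classes, and each library left out for the other classes, the class shares, the lists within classes and the interaction. Where a library was left out, the lone library of its group was assumed to vary like the other group. An adjusted p that DESeq2 did not give was left as missing. The raw matrices were used only for the ambient profile.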

Results

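Transcripts of single nuclei were measured in the hippocampus of aged mice. There were 2 control libraries with a non-targeting guide and 2 libraries labelled Ftl1 cKO with a guide against Ftl1, the light chain of the iron-storage protein ferritin. After filtering, the control libraries held 11809 and 12528 nuclei with a median of 3725 and 3451 UMIs. The libraries labelled Ftl1 cKO held 11268 and 12842 nuclei with a median of 3574 and 3990.5 UMIs. Named neuronal classes made up 27945 of the 48447 nuclei. The 6255 nuclei of unnamed clusters, some of them neuronal by Snap25 and Rbfox3, were left out of the neuronal sum. The comparison asks what changes in aged hippocampal neurons when neuronal FTL1, which rises with age according to the series description, is targeted.

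RNA of the targeted gene, Ftl1, was higher, not lower, in the neuronal nuclei of both libraries labelled Ftl1 cKO. Ftl1 (ENSMUSG00000050708, mm10 chromosome 7, 45457944 to 45459884) stood at 17.9 and 15.8 CPM in the control libraries and at 31.6 and 29.4 CPM in the libraries labelled Ftl1 cKO. Its log2 fold was 0.86 (SE 0.10, n = 2 against 2, edgeR adjusted p = 0.00477). By class, the log2 fold was 0.91 (SE 0.12) in dentate granule-like, 0.71 (SE 0.15) in CA1-like, 1.14 (SE 0.20) in CA3-like and 0.80 (SE 0.16) in GABAergic-like nuclei, each past the threshold. Fth1, the heavy chain of ferritin (ENSMUSG00000024661, chromosome 19, 9980598 to 9985098), rose in neuronal nuclei with a log2 fold of 0.78 (SE 0.07, edgeR adjusted p = 0.00176). The titles of the libraries labelled Ftl1 cKO name FH1, while their treatment labels and the series description name Ftl1, and which is meant by the titles is not given in the sources used here. For this reason Fh1, the fumarase of the TCA cycle, was measured as well, and it did not pass the test (log2 fold 0.23, SE 0.10, edgeR adjusted p = 0.278). A 3' count does not check the edit, because a small insertion or deletion need not lower the RNA and the cut site is not given in the sources used here. Moreover, the vector transcript CreWpre was found in only 0.341% and 5.90% of the neuronal nuclei of the libraries labelled Ftl1 cKO.

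The neuronal Ftl1 call was lost when all nuclei were summed (log2 fold 0.69, edgeR adjusted p = 0.162) and when a trend on gene span was removed (0.48, 0.257). It was also lost with ambient RNA removed at the bound that glial and endothelial markers set (2.12, 0.426) and in the few nuclei with a vector UMI (0.61, 1). Over the alternatives that could test it, the adjusted p of this call ran from 1.50e-09 to 1. With 10% ambient RNA removed, or at the bound of glial markers alone, neuronal Ftl1 and Fth1 could not be tested. Nor could Ftl1 in the classes below. Neuronal Ftl1 lay at 4.69% to 6.65% of its level in barcodes of at most 100 UMIs. The glial bound removed 13.3% to 17.2%, so it cannot decide whether the Ftl1 rise is ambient RNA. The log2 fold of 2.12 had an SE of 1.01. The neuronal Fth1 call was lost when all nuclei were summed (log2 fold 0.73, edgeR adjusted p = 0.166), when the trend on gene span was removed (0.53, 0.0533) and in nuclei with a vector UMI (0.22, 1), with a range over the alternatives of 8.02e-16 to 1. Without Ftl1 cKO replicate 1, the Ftl1 call was lost in CA1-like (0.65, edgeR adjusted p = 0.101), CA3-like (0.97, 0.0621) and GABAergic-like nuclei (0.57, 0.178). DESeq2 did not call Ftl1 in CA1-like (0.70, adjusted p = 0.0672) or CA3-like nuclei (1.15, 0.182), and gave it no adjusted p in GABAergic-like nuclei (0.81). With the trend on gene span removed, the call was lost in dentate granule-like (0.50, edgeR adjusted p = 0.262), CA1-like (0.34, 0.651), CA3-like (0.81, 0.370) and GABAergic-like nuclei (0.46, 0.558). At the ambient bound with endothelial markers it was lost in dentate granule-like (1.93, edgeR adjusted p = 0.275) and GABAergic-like nuclei (1.73, 0.558). In CA3-like nuclei it was also lost with classes set by each nucleus's own markers (0.89, 0.119) and in nuclei without a CreWpre UMI (1.17, 0.0520). Over the alternatives the adjusted p of Ftl1 ran from 1.47e-08 to 0.275 in dentate granule-like, from 4.03e-05 to 0.651 in CA1-like, from 1.78e-07 to 0.370 in CA3-like and from 4.26e-05 to 0.558 in GABAergic-like nuclei.

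**Figure D1:**
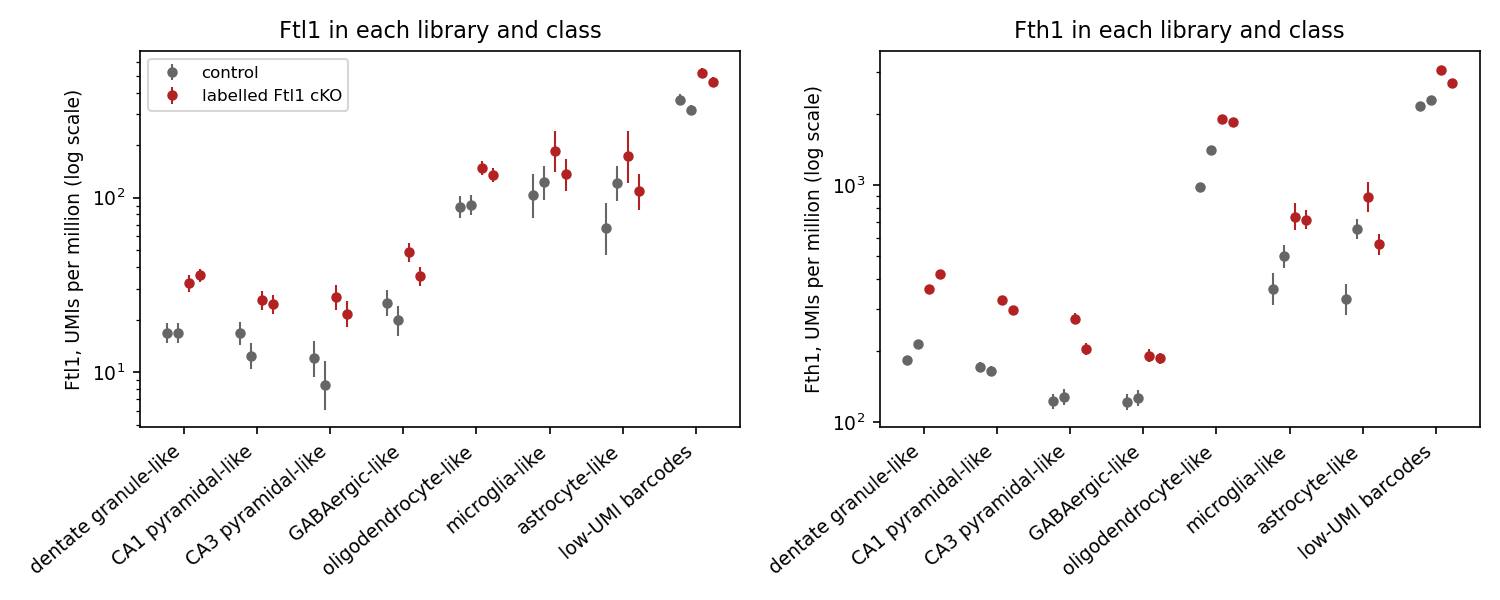
UMIs (log scale, CPM) of Ftl1 (left) and Fth1 (right) in each library, for 7 cell classes and for barcodes of at most 100 UMIs; each point is a library, with its exact 95% Poisson interval. In barcodes of at most 100 UMIs, Ftl1 stood at 363 and 320 CPM in the controls and at 521 and 462 CPM in the libraries labelled Ftl1 cKO.

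In all neuronal nuclei of named clusters, 222 of 15091 genes passed the edgeR threshold, 192 higher and 30 lower in the libraries labelled Ftl1 cKO. In these libraries Ftl1 RNA was higher, not lower. The genes that rose included 54 cytosolic ribosomal proteins. Among the largest rises were those of the ribosomal protein genes Rps16 (log2 fold 0.95, SE 0.12), Rpl34 (0.93, SE 0.15), Rps19 (0.89, SE 0.13), Rpl35 (0.83, SE 0.13) and Rpl39 (0.78, SE 0.10), beside Ftl1 and Fth1. The actin-binding peptide gene Tmsb10 (0.90, SE 0.12), the neuropeptide genes Sst (0.88, SE 0.15) and Npy (0.87, SE 0.12), and Smim26 (0.80, SE 0.17) rose as well. Sst and Npy are also markers of the GABAergic class, whose nuclei are in this sum. The largest falls were those of Pde3a, a cyclic nucleotide phosphodiesterase (log2 fold -0.59, SE 0.12), Muc15 (-0.47, SE 0.10), the glypican gene Gpc5 (-0.41, SE 0.08) and the Notch coactivator gene Maml3 (-0.40, SE 0.07). Stxbp6 (-0.39, SE 0.07), the activin subunit gene Inhba (-0.38, SE 0.08), Marchf3 (-0.37, SE 0.08) and Pigk (-0.35, SE 0.07) followed. Adarb2 (-0.35, SE 0.07), Glis3 (-0.35, SE 0.07), Lrtm1 (-0.35, SE 0.07) and the ion exchanger gene Slc24a4 (-0.34, SE 0.07) fell too. Stxbp6 and Glis3 are also markers of the dentate granule class and Adarb2 of the GABAergic class. Adarb2 and Pde3a lead a GABAergic-like cluster. With called doublets included, it held 314 and 272 control nuclei and 208 and 281 nuclei of the libraries labelled Ftl1 cKO.

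The median span was 3653 bp for the genes that rose, 313452 bp for those that fell and 26690 bp for all tested genes. The count of 222 was 1608 without control replicate 1, 791 without control replicate 2 and 106 without Ftl1 cKO replicate 2. With DESeq2 it was 462, of which 67.7% were higher against 86.5% with edgeR. Of the 24 genes that the naming rule takes by size of change, not all of them named here, 1 lost its call without control replicate 1, 2 without control replicate 2, 4 without Ftl1 cKO replicate 1 and 9 without Ftl1 cKO replicate 2. With 10% ambient RNA removed, 17 of the 18 that could still be tested lost it, at the glial bound 13 of 15, and at the bound with endothelial markers 7 of 24. All 24 lost it with the trend on gene span removed and with all nuclei summed. With edgeR the count was 0 when a trend on gene span was removed (1278 genes at an unadjusted p under 0.05), 0 when all nuclei were summed (2266 genes) and 0 in nuclei with a CreWpre UMI (74 genes). DESeq2 was not run on those sums.

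**Figure D2:**
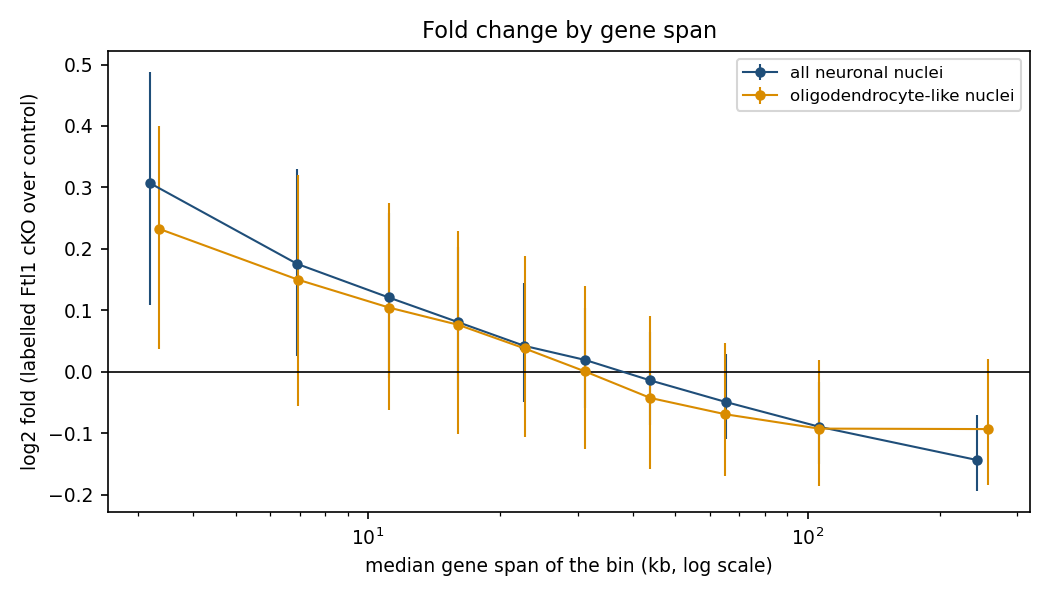
Median log2 fold (libraries labelled Ftl1 cKO over controls) of genes in 10 bins of gene span (kb, log scale) in all neuronal nuclei and in oligodendrocyte-like nuclei; bars run from the lower to the upper quartile of genes. The median fell from 0.31 in the bin of the shortest genes to -0.14 in that of the longest in neuronal nuclei, and from 0.23 to -0.09 in oligodendrocyte-like nuclei.

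Among the functional lists, 15 of 18 passed camera at the preset correlation in all neuronal nuclei, 12 higher and 3 lower in the libraries labelled Ftl1 cKO. None passed with an estimated correlation (lowest adjusted p = 0.338). With 2 against 2 libraries and no simulation of its power, that setting cannot decide whether a list changed. Cytosolic ribosomal proteins, which build the ribosome, rose together, with a median log2 fold of 0.57 (camera adjusted p = 5.31e-56). Of 80 measured genes, 54 rose past the threshold over all genes and 78 adjusted over the list alone. Rpl13 (log2 fold 0.67, SE 0.07), Rpl41 (0.60, SE 0.07), Rplp1 (0.70, SE 0.08) and Rps13 (0.58, SE 0.07) had the smallest p. The respiratory chain lists, whose proteins make ATP in mitochondria, were higher. Of 36 complex I genes, 3 passed the threshold and 22 adjusted over the list alone (median 0.38, adjusted p = 4.6e-15). Of 26 genes of complexes II to IV, 6 passed and 21 adjusted over the list alone (median 0.40, adjusted p = 5.93e-15). Of 19 ATP synthase genes, 3 passed, and 14 were higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 8.98e-09). Examples that rose were Cox8a (log2 fold 0.63, SE 0.09), Uqcr10 (0.55, SE 0.10), Ndufb5 (0.52, SE 0.10) and Atp5md (0.47, SE 0.08). These 4 list calls were lost with an estimated correlation (adjusted p = 0.338 each), the highest over their alternatives. The lowest were 3.07e-106, 1.82e-34, 1.25e-28 and 2.14e-19. The same lists had medians of 0.42 (ribosomal proteins), 0.31, 0.29 and 0.27 in oligodendrocyte-like nuclei. For none of the functional lists did the alternatives include removal of the trend on gene span. In neuronal nuclei, all genes in the bin of the shortest genes (median span 3.2 kb) had a median log2 fold of 0.31. Whether the neuronal medians of these lists go beyond that trend was not tested. Without control replicate 1 the medians of the 3 respiratory chain lists in neuronal nuclei were 0.22, 0.26 and 0.17, still past the threshold. Without Ftl1 cKO replicate 2, Uqcr10, Ndufb5 and Atp5md did not pass.

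Activity-regulated genes, the immediate early genes that neurons switch on after firing, had a median log2 fold of 0.64, all 20 measured members above 0 (camera adjusted p = 1.92e-10). Of these, Ier2 (log2 fold 1.25, SE 0.23) and Fosb (1.65, SE 0.33) passed the threshold over all genes and 10 genes adjusted over the list alone. DESeq2 gave no adjusted p for Ier2 (log2 fold 1.25) or Fosb (1.64). Junb stood at 0.97 (SE 0.18, edgeR adjusted p = 0.0518). Heat shock and unfolded protein response genes had a median of 0.39 (adjusted p = 3.95e-10). The chaperone gene Hspa8 (0.49, SE 0.06) and the stress transcription factor gene Atf4 (0.60, SE 0.13) passed the threshold, and 13 of 18 genes adjusted over the list alone. Lysosome and autophagy genes had a median of 0.11 (adjusted p = 0.0105). Map1lc3b (0.53, SE 0.10), Map1lc3a (0.55, SE 0.11) and Ctsb (0.41, SE 0.08) rose, and 8 of 23 genes passed adjusted over the list alone. Glycolysis genes had a median of 0.18 (adjusted p = 0.000163), with Ldha (0.48, SE 0.10) past the threshold and 3 of 19 adjusted over the list alone. Each of these list calls was lost with an estimated correlation (adjusted p = 0.338), the highest over their alternatives. In the order given, the lowest were 5.95e-22, 3.33e-11, 0.000854 and 1.38e-08. Without control replicate 2 the median of the activity-regulated genes was 0.38. Without Ftl1 cKO replicate 2 the glycolysis median was 0.11, and Fosb, Atf4, Map1lc3b, Map1lc3a, Ctsb and Ldha did not pass; Atf4 and Map1lc3b did not pass without Ftl1 cKO replicate 1 either.

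Of the synaptic lists, those of the excitatory postsynapse and the inhibitory synapse were lower. Over all genes in neuronal nuclei, the median log2 fold was -0.090 and -0.14 in the bins of the longest genes (median spans 106 and 243 kb). The synaptic lists were not tested with the trend on gene span removed. Whether their medians go beyond that trend is therefore undecided. The excitatory postsynapse list had a median log2 fold of -0.12 (camera adjusted p = 6.7e-06), with no gene past the threshold over all genes and 6 lower and 1 higher of 30 adjusted over the list alone. The AMPA receptor gene Gria1 stood at -0.21 (SE 0.06) and the NMDA receptor gene Grin2a at -0.24 (SE 0.06). The inhibitory synapse list had a median of -0.10 (adjusted p = 0.0314), with 6 lower and 2 higher of 19 adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.338, with a range over the alternatives of 5.58e-07 to 0.338 for the excitatory postsynapse). That of the inhibitory synapse was also lost without control replicate 1 (median -0.16, adjusted p = 0.0552) and without control replicate 2 (-0.051, 0.170), with 10% ambient RNA removed (-0.099, 0.177) and at the glial bound (-0.085, 0.218), with a range over the alternatives of 0.0126 to 0.338. Its median was -0.15 without Ftl1 cKO replicate 1. Presynaptic vesicle release genes did not pass (median -0.016 and mean 0.0095, adjusted p = 0.279), although Vamp2 rose (0.39, SE 0.08). Vamp2 did not pass without Ftl1 cKO replicate 1 or 2.

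Iron handling genes other than Ftl1 did not pass as a list (median log2 fold 0.092, camera adjusted p = 0.139), and of its 28 measured genes Fth1 alone passed the threshold. The transferrin receptor gene Tfrc stood at 0.36 (SE 0.11, edgeR adjusted p = 0.130) and the iron chaperone gene Pcbp1 at 0.41 (SE 0.13, edgeR adjusted p = 0.127). The ferroptosis and antioxidant list had a median of 0.094 (adjusted p = 0.0375, and 0.338 with an estimated correlation), with no gene past either threshold. Gpx4, a peroxidase that removes lipid peroxides, stood at 0.48 (SE 0.12). Mitochondrially encoded genes had a median of 0.46 (adjusted p = 0.000477, and 0.409 with an estimated correlation) with no gene past either threshold. That median was -0.000324 without control replicate 1 (adjusted p = 0.855), 0.98 without control replicate 2 and 0.24 without Ftl1 cKO replicate 2. Its adjusted p ran from 1.44e-26 to 0.855 over the alternatives. TCA cycle genes did not pass (median 0.054, adjusted p = 0.158).

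The neurite cytoskeleton list (median 0.16, adjusted p = 0.0256) and the p53 and DNA damage list (median 0.18, adjusted p = 0.0168) passed at the preset correlation only. Each had an adjusted p of 0.338 at an estimated correlation and no gene past the threshold over all genes, with 4 of 26 and 0 of 17 genes past it adjusted over the list alone. The interferon and antigen presentation list had a median of -0.39 (adjusted p = 0.0375, and 0.473 with an estimated correlation), with no gene past either threshold. Its median was 0.22 without control replicate 2 (adjusted p = 0.220) and -0.93 without control replicate 1, with an adjusted p from 1.13e-10 to 0.859 over the alternatives. The ferroptosis call was lost without control replicate 1 (adjusted p = 0.233) and without Ftl1 cKO replicate 2 (0.171). The p53 call was lost without control replicate 2 (0.186) and without Ftl1 cKO replicate 1 (0.0874), and the neurite cytoskeleton call without Ftl1 cKO replicate 2 (0.109). The neurite cytoskeleton median was 0.086 without control replicate 2 and 0.25 without Ftl1 cKO replicate 1, and the ferroptosis median 0.14 without control replicate 2. With 10% ambient RNA removed, the ferroptosis (adjusted p = 0.110) and p53 calls (0.130) were lost as well, and so they were at the glial bound (0.102 and 0.224). The interferon call was lost with 10% ambient RNA removed (0.859), at the glial bound (0.849), at the bound with endothelial markers (0.674) and with matched numbers (0.0563). Over the alternatives, the adjusted p of these 3 lists, in the order ferroptosis, p53 and neurite cytoskeleton, ran from 0.00644, 0.0134 and 5.02e-05 to 0.338. The TCA cycle list passed without control replicate 2 (adjusted p = 0.0211) and the iron handling list without Ftl1 cKO replicate 1 (0.0435). Over the alternatives their adjusted p ran from 0.0211 to 0.815 and from 0.0435 to 0.677. Camera called 0 of the 18 marker lists in all neuronal nuclei (lowest adjusted p = 0.146, and 0.849 with an estimated correlation).

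**Figure D3:**
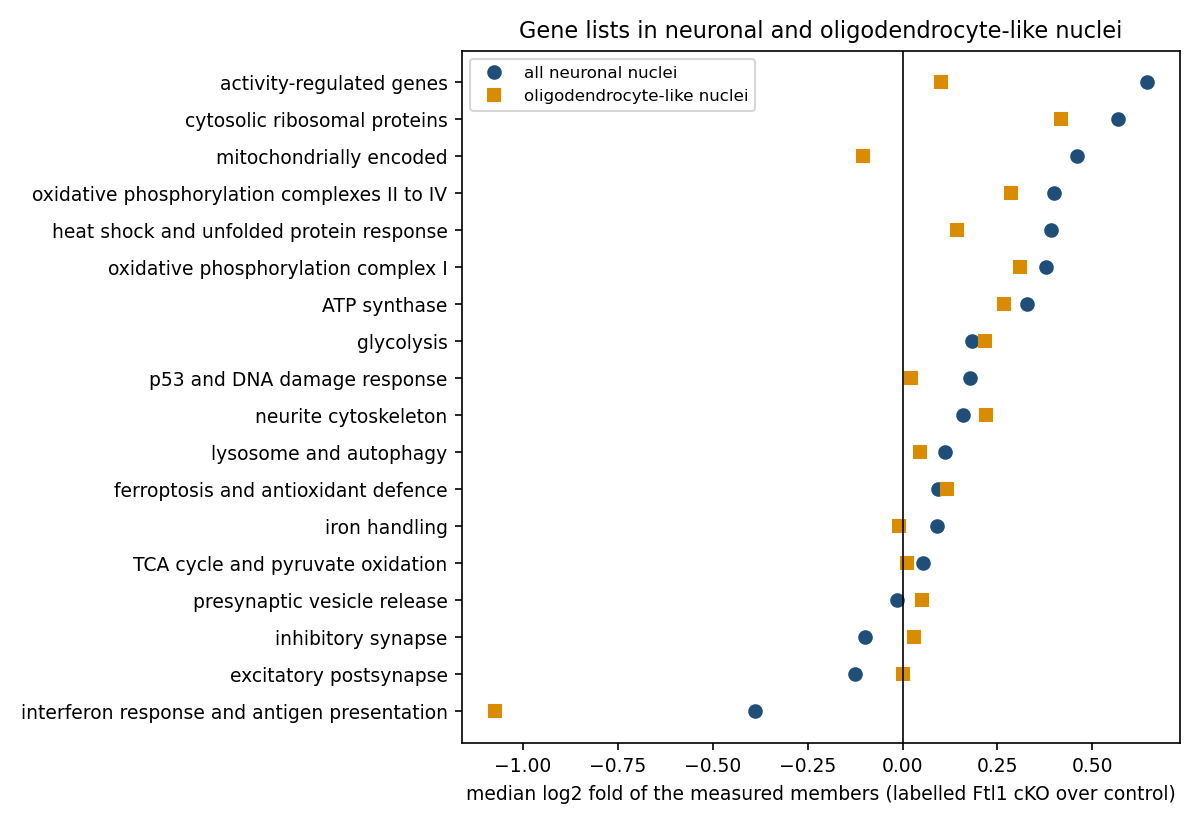
Median log2 fold (libraries labelled Ftl1 cKO over controls) of the measured members of each functional list in all neuronal nuclei (circles) and in oligodendrocyte-like nuclei (squares). Cytosolic ribosomal proteins stood at 0.57 and 0.42, and the interferon list at -0.39 and -1.07.

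In dentate granule-like nuclei, 78 of 12927 genes passed, 74 higher and 4 lower in the libraries labelled Ftl1 cKO. The largest rises were those of Rpl34 (log2 fold 1.11, SE 0.14), Rpl35 (1.07, SE 0.14), Rps16 (1.02, SE 0.11), Arxes1 (1.01, SE 0.19) and Rps19 (0.93, SE 0.12). The genes that fell were the cadherin gene Cdh11 (-0.41, SE 0.08), Cntnap5b (-0.34, SE 0.07), Brinp1 (-0.34, SE 0.07) and Dnajc1 (-0.34, SE 0.07). The count was 323 without control replicate 1, 470 without control replicate 2, 1225 without Ftl1 cKO replicate 1 and 3 with the trend on gene span removed. Cdh11, Brinp1 and Dnajc1 lost their call without control replicate 1, Cntnap5b without control replicate 2 and Arxes1 without Ftl1 cKO replicate 2. Of the 9 genes named here, 5 lost their call with 10% ambient RNA removed, 5 of 5 still tested at the glial bound, and 9 with the trend on gene span removed.

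In CA1-like nuclei, 207 of 12696 genes passed, 190 higher and 17 lower. Mcts2 (log2 fold 1.13, SE 0.21), the immediate early gene Junb (1.12, SE 0.14), Rps16 (1.06, SE 0.14), the growth factor signalling inhibitor gene Spry2 (1.03, SE 0.17) and Rps19 (0.91, SE 0.16) rose most. The potassium channel gene Kcnj13 (-0.61, SE 0.16), also a choroid plexus marker, Megf11 (-0.55, SE 0.14), the inositol kinase gene Itpkb (-0.54, SE 0.14), Car10 (-0.49, SE 0.09) and the proteoglycan gene Spock1 (-0.46, SE 0.09) fell most. The count was 666 without control replicate 1, 341 without control replicate 2, 79 without Ftl1 cKO replicate 1, 90 without Ftl1 cKO replicate 2, 58 with DESeq2 and 5 with the trend on gene span removed. Of these 10 genes, 1 and 2 lost their call without control replicate 1 and 2, and 6 and 4 without Ftl1 cKO replicate 1 and 2. With the trend on gene span removed 9 lost it, with classes set by each nucleus's own markers 5, and with 10% ambient RNA removed 4 of 8 still tested; Car10 stood at 0.066 with classes set by each nucleus's own markers.

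In CA3-like nuclei, 22 of 11714 genes passed, all higher. Ftl1, Rps19 (log2 fold 1.13, SE 0.22), Rpl34 (1.13, SE 0.19), Septin1 (1.12, SE 0.22) and Junb (1.09, SE 0.21) rose most. The count was 584 without control replicate 1, where Septin1 stood at 1.73, 148 without control replicate 2, 66 without Ftl1 cKO replicate 2 and 1 with DESeq2. It was 0 by edgeR with the trend on gene span removed (606 genes at an unadjusted p under 0.05). Ftl1, Rps19 and Rpl34 lost their call without Ftl1 cKO replicate 1, and DESeq2 called none of the 5 genes named here. All 5 also lost it in nuclei without a CreWpre UMI and with the trend on gene span removed, and 4 with classes set by each nucleus's own markers.

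In GABAergic-like nuclei, 66 of 12294 genes passed, 46 higher and 20 lower. The sterol regulator gene Insig1 (log2 fold 0.98, SE 0.20), the histone gene H2bc27 (0.90, SE 0.19), Npy (0.87, SE 0.11), Sf3b5 (0.87, SE 0.19) and Rtl8a (0.85, SE 0.17) rose most. Pde3a (-0.72, SE 0.10), the estrogen receptor gene Esr1 (-0.72, SE 0.15), Cpne2 (-0.71, SE 0.16), Cadps2, which serves vesicle exocytosis (-0.68, SE 0.08), and Rgs12 (-0.60, SE 0.12) fell most. Pde3a and Rgs12 lead the GABAergic-like cluster whose nuclei, called doublets included, numbered 314 and 272 in the control libraries. They numbered 208 and 281 in the libraries labelled Ftl1 cKO. The count was 537 without control replicate 1, 233 without control replicate 2, 7 with the trend on gene span removed and 32 with DESeq2, of which 34.4% were higher against 69.7% with edgeR. Of these 10 genes, 1 lost its call without control replicate 1, 1 without control replicate 2, 3 without Ftl1 cKO replicate 1 and 5 without Ftl1 cKO replicate 2. With doublets kept 5 lost it, at the glial bound 7 and with the trend on gene span removed 7. DESeq2 gave an adjusted p for only 3 of these 10 genes, which kept their call.

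At the preset correlation, 11 of 18 functional lists passed camera in dentate granule-like, 12 in CA1-like, 10 in CA3-like and 8 in GABAergic-like nuclei. Ribosomal proteins had medians of 0.66, 0.57, 0.58 and 0.41 in that order, and activity-regulated genes 0.63, 0.73, 0.94 and 0.22. None passed with an estimated correlation, at which the lowest adjusted p was 0.362, 0.298, 0.390 and 0.356.

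The test of whether the effect differed from that in dentate granule-like nuclei called 0 of 13707 genes for CA1-like (733 at an unadjusted p under 0.05, edgeR, DESeq2 not run), 1 for CA3-like and 7 for GABAergic-like nuclei. Except Parp8, these were mitochondrially encoded genes. As an example, mt-Co1, a subunit of cytochrome oxidase, had a log2 fold of 0.89 (SE 0.33) in dentate granule-like and of 0.083 (SE 0.29) in GABAergic-like nuclei. The difference was -0.80 (SE 0.11, edgeR adjusted p = 0.000495). Without control replicate 1 the counts for CA1-like, CA3-like and GABAergic-like nuclei were 5, 5 and 11, and without Ftl1 cKO replicate 1 they were 9, 20 and 30. Without control replicate 2 they were 0 (815 unadjusted, edgeR), 2 and 1, and without Ftl1 cKO replicate 2 they were 0 (684 unadjusted, edgeR), 0 (655) and 5.

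Among the other classes, 242 of 12789 genes passed in subicular or cortical excitatory-like nuclei (144 higher, 98 lower; 220 with DESeq2). In CA2-like nuclei 22 of 8778 genes passed (596 at an unadjusted p under 0.05), and 0 with DESeq2. With edgeR, 0 genes passed in oligodendrocyte-like (681 at an unadjusted p under 0.05), oligodendrocyte precursor-like (453) and astrocyte-like nuclei (237), with 0 by DESeq2 in each. In microglia-like nuclei 1 gene passed (392 at an unadjusted p under 0.05, 0 with DESeq2). It was Fcrls, an Fc receptor-like gene of microglia (log2 fold 1.17, SE 0.20, edgeR adjusted p = 0.0493), chosen after its value was seen. The 192 genes that rose in neuronal nuclei were mostly above 0 in oligodendrocyte-like nuclei, 184 of 186 tested. Their median log2 fold there was 0.37, against 0.56 in neuronal nuclei. It was 0.39 in oligodendrocyte precursor-like (148 of 168 above 0), 0.33 in astrocyte-like (155 of 170) and 0.34 in microglia-like nuclei (152 of 165). Ftl1 did not pass in oligodendrocyte-like (log2 fold 0.61, SE 0.13, edgeR adjusted p = 0.254), oligodendrocyte precursor-like (0.18, SE 0.19, 0.970), microglia-like (0.44, SE 0.23, 0.966) or astrocyte-like nuclei (0.47, SE 0.35, 1.00).

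Counts in the other classes moved with single libraries. Without control replicate 1 and without control replicate 2, they were 114 and 194 in oligodendrocyte-like, 11 and 12 in precursor-like, 40 and 338 in astrocyte-like and 115 and 50 in microglia-like nuclei. They were 766 and 543 in subicular or cortical and 34 and 7 in CA2-like nuclei. Without Ftl1 cKO replicate 1 and without Ftl1 cKO replicate 2, they were 0 and 0 in oligodendrocyte-like nuclei (558 and 217 at an unadjusted p under 0.05, edgeR, DESeq2 not run). They were then 24 and 3 in precursor-like, 1 and 1 in astrocyte-like, 2 and 3 in microglia-like, 79 and 182 in subicular or cortical and 6 and 10 in CA2-like nuclei.

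Oligodendrocyte-like nuclei made up 18.3% and 17.9% of the control libraries and 24.5% and 21.3% of the libraries labelled Ftl1 cKO. The means were 18.1% ± 0.28 and 22.9% ± 2.21 (SD, n = 2 each; exact permutation p = 0.333, the smallest these libraries allow). Dentate granule-like nuclei made up 22.9% ± 0.854 of the control libraries and 20.7% ± 1.12 of the libraries labelled Ftl1 cKO (SD, n = 2 each; exact permutation p = 0.333). CA1-like nuclei made up 13.6% ± 0.678 and 11.7% ± 1.12 (exact permutation p = 0.333), and subicular or cortical excitatory-like nuclei 8.85% ± 0.0966 and 10.3% ± 1.37 (exact permutation p = 0.333). The dentate granule-like difference of -2.25 percentage points was -1.46 without Ftl1 cKO replicate 1, and the CA1-like difference of -1.95 was -1.16 without Ftl1 cKO replicate 2. The subicular or cortical difference of 1.43 was 0.465 without Ftl1 cKO replicate 1 and 2.40 without Ftl1 cKO replicate 2, and 0.639 at a clustering resolution of 0.5 (exact permutation p = 0.667). The sort and the dissection can set such shares.

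The vector transcript CreWpre was found in 204 of 2798 dentate granule-like nuclei of control replicate 2 (7.29%, exact 95% interval 6.35 to 8.32) and in 326 of 2758 of Ftl1 cKO replicate 2 (11.8%, 10.6 to 13.1). It was found in 6 of 2780 of control replicate 1 (0.216%, 0.0792 to 0.469) and in 2 of 2242 of Ftl1 cKO replicate 1 (0.0892%, 0.0108 to 0.322). Oligodendrocyte-like nuclei, in which a Synapsin promoter is silent, had 0.185%, 0.980%, 0.218% and 0.840% in the order control 1, control 2, Ftl1 cKO 1 and Ftl1 cKO 2. Their median was 969 to 1084 UMIs against 3930.5 to 4695.5 in dentate granule-like nuclei. With each nucleus thinned to 800 UMIs, the share in the same order was 0.0590%, 1.61%, 0.0154% and 2.58% in dentate granule-like nuclei (0, 1, 3 and 0 nuclei left out). It was 0.0988%, 0.560%, 0.153% and 0.587% in oligodendrocyte-like nuclei (570, 542, 558 and 565 left out). Astrocyte-like nuclei, which were few, had thinned shares of 0.181%, 2.26%, 0% and 1.17%. In control replicate 2 the astrocyte-like share was above the dentate granule-like one, while those of precursor-like (0.633%) and microglia-like nuclei (0.690%) were below it. The CreWpre share in control replicate 2 thus differed between glial classes. Whether the astrocyte-like share is background was not tested. In the libraries with replicate number 1, the thinned share in dentate granule-like nuclei was not above that in oligodendrocyte-like nuclei. In the few CA2-like nuclei it was 0.556% in control replicate 1 and 0.187% in Ftl1 cKO replicate 1. In barcodes of at most 100 UMIs, CreWpre stood at 29.3, 54.7, 33.1 and 50.5 CPM in the order control 1, control 2, Ftl1 cKO 1 and Ftl1 cKO 2. The vector transcript was thus present in every library. Within Ftl1 cKO replicate 2, Ftl1 stood at 30.2 CPM (exact 95% interval 22.97 to 38.9) in dentate granule-like nuclei with a CreWpre UMI and at 36.7 CPM (33.4 to 40.2) in those without, so a difference was not detectable at this depth.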

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

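Of the tests in this part, those of the gene span trend, of both ambient bounds set by markers, of a difference in preparation, of an effect confined to neurons, of an immune state of control replicate 2 and of haemoglobin, and the refits of the class interaction without single libraries, were chosen after the results were seen.

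The rise of Ftl1, Fth1 and the ribosomal protein transcripts in neuronal nuclei of the libraries labelled Ftl1 cKO is opposite to what a loss of Ftl1 RNA would give, although an insertion or deletion need not lower the RNA; an exchange of the group labels, which would turn every direction, was not tested and stays open, since the guide features held 1 and 2 UMIs in the barcodes called as nuclei. A candidate explanation is a difference in preparation that touched nuclei of every class: in oligodendrocyte-like nuclei the genes that rose had a median log2 fold of 65.8% of their neuronal median, and 184 of 186 were above 0, and their medians were 0.39 in oligodendrocyte precursor-like, 0.33 in astrocyte-like and 0.34 in microglia-like nuclei, although Ftl1 itself stood at 0.18 (SE 0.19) in the precursor-like nuclei. An effect of the edit confined to neurons predicts a share of under 25%, against the same 65.8%, and in Ftl1 cKO replicate 1 Ftl1 was as high in neuronal nuclei (32.4 CPM) as in Ftl1 cKO replicate 2 (30.7 CPM) with CreWpre at background (0.0892% of dentate granule-like nuclei), but it cannot be told apart, since few nuclei of any library held a CreWpre UMI, calls over all genes in oligodendrocyte-like nuclei rest on single libraries (0 by edgeR, 681 at an unadjusted p under 0.05, 0 by DESeq2, but 114 and 194 by edgeR without control replicate 1 and 2, and 0 and 0 without Ftl1 cKO replicate 1 and 2, with 558 and 217 unadjusted) and free neuronal RNA can carry a change into glia, where 61 of 79 ribosomal protein genes passed adjusted over the list alone. CreWpre at background in nuclei does not show that Ftl1 cKO replicate 1 lacked the vector. In barcodes of at most 100 UMIs, CreWpre stood at 33.1 CPM in that library and at 50.5 CPM in Ftl1 cKO replicate 2. Free RNA also stays open. Removing it at the bound set by glial markers left 324% of the median fold, but only 133 of the 192 genes, without Ftl1, could still be tested. The bound with endothelial markers left 144% while taking more from the controls (2.67% and 4.31%) than from the libraries labelled Ftl1 cKO (2.05% and 2.07%). The haemoglobin gene Hbb-bs went the other way, at 0.442% and 0.273% of its level in barcodes of at most 100 UMIs in the controls and at 1.51% and 2.53% in the libraries labelled Ftl1 cKO. Whether its UMIs in neuronal nuclei are free RNA was not tested. Removing the trend on gene span left 56.3% of the Ftl1 fold, from 0.86 (SE 0.10) to 0.48 (SE 0.12), and ended the call. Fth1 was left at 0.53 of 0.78 (SE 0.07 each), no longer past the threshold in all neuronal nuclei but past it in dentate granule-like (0.61) and CA1-like nuclei (0.57). The genes that rose were left at a median of 0.31 of 0.56. A shift from long to short transcripts may account for part of the rise, and the rest is undecided.

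The lower median of the interferon and antigen presentation list in neuronal nuclei of the libraries labelled Ftl1 cKO (-0.39) may come from an immune state of control replicate 2 alone, since without that library the median was 0.22. Control replicate 2 also held 116 of the 130 nuclei of an unnamed cluster led by interferon-inducible genes, closest to oligodendrocytes by its markers, and 58 T cell-like nuclei, against 10, 2 and 10 in the other libraries. Free RNA of the libraries was tested by removing 10%, after which the median was 0.00742, but only 4 of 18 list genes could still be tested, and those 4 had a median of 0.034 before removal, so this explanation cannot be told apart. An effect of the group on interferon genes stays open as well, with no further test.

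The log2 fold differed between GABAergic-like and dentate granule-like nuclei, by an interaction test in edgeR, for mt-Co1 (log2 difference -0.80), mt-Co2 (-0.78), mt-Nd2 (-0.98), mt-Nd4 (-0.98), mt-Atp6 (-0.99), mt-Cytb (-0.84) and Parp8 (0.43), and between CA3-like and dentate granule-like nuclei for mt-Co1 (-0.75). None of these genes passed in any of these classes alone. In barcodes of at most 100 UMIs, mitochondrially encoded UMIs made up 1.39% and 1.36% in the libraries labelled Ftl1 cKO. They made up 0.989% and 0.830% in the controls. Whether free RNA gave these differences between classes was not tested. Without control replicate 2 none of these 8 differences passed (adjusted p from 0.199 to 0.832), while all kept their sign. Without Ftl1 cKO replicate 2 those of mt-Co1 and mt-Nd4 in GABAergic-like nuclei alone passed, and without control replicate 1 those of Parp8, mt-Atp6 and mt-Co1 in CA3-like nuclei did not.

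In barcodes of at most 100 UMIs, which the comparisons did not use, Ftl1 stood at a mean of 491 CPM in the libraries labelled Ftl1 cKO against 363 and 320 CPM in the controls. Fth1 stood at a mean of 2878 CPM there against 2156 and 2289 CPM. Mitochondrially encoded UMIs made up 1.38% of UMIs in those barcodes of the libraries labelled Ftl1 cKO against 0.989% and 0.830% in the controls.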

How the results depend on the processing

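Chosen after the data were examined were the removal of the gene span trend, both removals of ambient RNA at marker bounds, the choice of nuclei by CreWpre, the estimated correlation within classes, DESeq2 in the other classes, and the left-out libraries for the other classes, the class shares, the lists within classes and the interaction; the other tests here were planned. Over 2436 checks of a named gene under an alternative, 1854 kept their direction and side of the threshold, 163 newly passed, 399 no longer passed and 20 changed sign; over 196 checks of a list in neuronal nuclei these numbers were 153, 3, 30 and 10, and of 231 checks of counts and shares 129 stayed close, 91 moved and 11 changed sign. DESeq2 gave no adjusted p in 24 checks of a named gene in a class, which are not counted. With 10% ambient RNA removed, Ftl1 and Fth1 could no longer be tested in all neuronal nuclei, where Ftl1 lay at 4.69% to 6.65% and Fth1 at 6.92% to 10.7% of its level in barcodes of at most 100 UMIs. Depth was a limit where CreWpre-positive nuclei were too few for a test in CA1-like, CA3-like and GABAergic-like nuclei. CA2-like nuclei did not form a cluster at resolution 0.5. Except where fewer nuclei, libraries or genes show it, the cause was not tested.

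The counts of changed genes in all neuronal, dentate granule-like, CA1-like, CA3-like and GABAergic-like nuclei were 222, 78, 207, 22 and 66. With DESeq2 they were 462 in all neuronal, 58 in CA1-like, 1 (Pcsk1n) in CA3-like and 32 in GABAergic-like nuclei, and without a filter on low counts 504, 898, 381, 142 and 272. The share of higher genes was 67.7% with DESeq2 and 75% without a filter in all neuronal nuclei (86.5% in the reported test), 57.5% without a filter in dentate granule-like (94.9%), 83.1% without a filter in CA3-like (100%) and 34.4% with DESeq2 in GABAergic-like nuclei (69.7%). With 10% ambient RNA removed the counts were 105 in all neuronal, 99 in CA1-like and 133 in GABAergic-like nuclei; with ambient RNA removed at the bound with endothelial markers 565, 169, 383, 136 and 146; at the glial bound 0 in dentate granule-like (edgeR, 1788 at an unadjusted p under 0.05, DESeq2 not run) and 9 in GABAergic-like nuclei. With classes by each nucleus's own markers they were 98 in CA1-like, 9 in CA3-like and 174 in GABAergic-like nuclei, with matched numbers 349 in all neuronal nuclei, and with all nuclei summed 0 (edgeR, 2266 unadjusted). With the gene span trend removed they were 0 (edgeR, 1278 unadjusted), 3, 5, 0 (606 unadjusted) and 7. CreWpre-positive nuclei gave 0 in all neuronal (edgeR, 74 unadjusted) and 1 (Cd200) in dentate granule-like nuclei, and CreWpre-negative nuclei 3 in CA3-like nuclei. With single libraries left out, the counts ran from 106 to 1608, from 95 to 1225, from 79 to 666, from 22 to 584 and from 67 to 537.

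Same-numbered libraries did not deviate together (correlation across genes of 0.007, 0.035, -0.080, -0.065 and 0.018), so their numbers were not taken to pair them, although the share of dentate granule-like nuclei with CreWpre went with the number (0.216% and 0.0892% for number 1, 7.29% and 11.8% for number 2). With a replicate block the counts were 788 in all neuronal, 579 in dentate granule-like, 258 in CA1-like, 86 in CA3-like and 238 in GABAergic-like nuclei, and no named gene or list lost its call.

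Ftl1 in all neuronal nuclei did not pass with all nuclei summed (0.69), with the span trend removed (0.48), at the bound with endothelial markers (2.12) or in CreWpre-positive nuclei (0.61), and ran from 0.76 to 0.94 with single libraries left out, each past the threshold. Named genes that changed sign in CreWpre-positive neuronal nuclei were Muc15 (0.17), Adarb2 (1.11), Gpx4 (-0.00109), Atp5e (-0.10), Pdha1 (-0.47), Tpi1 (-0.00147), Junb (-0.26), Tubb3 (-0.65), Atf4 (-0.019) and Gabarap (-0.29). With the span trend removed mt-Nd4l (-0.11), mt-Nd3 (-0.15), Plk2 (-0.00212) and Bax (-0.010) did, and with all nuclei summed Trim30a (-0.48). With own markers Car10 in CA1-like (0.066) and Fh1 in CA3-like nuclei (0.14) did. With libraries left out Fh1 did in dentate granule-like (from -0.073 to 0.42) and CA3-like nuclei (from -0.23 to 0.053) and mt-Nd3 in all neuronal nuclei (from -0.000324 to 0.97).

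With an estimated correlation 0 of 18 functional lists passed camera in all neuronal and 0 in dentate granule-like, CA1-like, CA3-like and GABAergic-like nuclei, against 15, 11, 12, 10 and 8. List medians changed sign for iron handling without control replicate 1 (from -0.000951 to 0.087), for the mitochondrially encoded list without control replicate 1 (-0.000324, up to 0.98 without control replicate 2) and for the interferon list without control replicate 2 (0.22, down to -0.93 without control replicate 1), with 10% ambient RNA removed (0.00742) and at the bound with endothelial markers (0.020). The presynaptic list, which did not pass, changed sign without control replicate 1 and without Ftl1 cKO replicate 1 (from -0.042 to 0.043 with libraries left out), with matched numbers (0.000222), with 10% ambient RNA removed (0.030) and at the glial bound (0.031).

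In the other classes DESeq2 called 0 genes in CA2-like (596 unadjusted in edgeR) and 0 in microglia-like nuclei (392). With single libraries left out the counts ran from 6 to 34 in CA2-like, from 79 to 766 in subicular or cortical, from 0 to 194 in oligodendrocyte-like, from 3 to 24 in precursor-like, from 1 to 338 in astrocyte-like and from 2 to 115 in microglia-like nuclei. Interaction counts for CA1-like, CA3-like and GABAergic-like nuclei were 15, 4 and 16 without a filter and ran from 0 to 9, from 0 to 20 and from 1 to 30 with libraries left out. The share difference of GABAergic-like nuclei (-0.0022 percentage points) was 0.0105 at resolution 0.5 and 0.0024 with doublets kept, and that of unnamed nuclei (0.327) was -0.464 with doublets kept. With libraries left out the differences changed sign for CA3-like (from -0.969 to 0.669), CA2-like (from -0.240 to 0.169), GABAergic-like (from -0.502 to 0.497), precursor-like (from -0.628 to 0.121), astrocyte-like (from -1.37 to 0.258), microglia-like (from -2.11 to 0.0809) and unnamed nuclei (from -1.14 to 1.79).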

Other observations

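The comparisons of gene lists in oligodendrocyte-like nuclei and of the values below were not planned and were chosen after the data were seen. In oligodendrocyte-like nuclei 8 of 18 functional lists passed camera at the preset correlation, 7 higher and 1 lower in the libraries labelled Ftl1 cKO, and 0 with an estimated correlation (lowest adjusted p = 0.460). Ribosomal protein genes had a median log2 fold of 0.42, with 79 of 79 above 0 and 61 past the threshold adjusted over the list alone, although edgeR called 0 over all genes (681 at an unadjusted p under 0.05, 0 by DESeq2). Complex I (0.31), complexes II to IV (0.29), ATP synthase (0.27), glycolysis (0.22), neurite cytoskeleton (0.22) and the heat shock list (0.14) were the others that were higher. The interferon and antigen presentation list had a median of -1.07 with 0 of 11 genes above 0 (camera adjusted p = 2.66e-07, and 0.579 with an estimated correlation). Without control replicate 2 it did not pass (adjusted p = 0.0888, range over the left-out libraries 3.18e-60 to 0.0888).

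T cell-like nuclei and an unnamed cluster led by interferon-inducible genes were unevenly spread over the libraries. T cell-like nuclei numbered 10 and 58 in the control libraries and 2 and 10 in the libraries labelled Ftl1 cKO. The cluster, led by the interferon-inducible GTPase genes Iigp1 and Igtp and the class I antigen presentation genes H2-D1 and H2-K1, was closest to the oligodendrocyte class, with 10 of its markers raised but none among the 10 leading genes, and held 5 and 116 nuclei of the control libraries and 0 and 9 of the libraries labelled Ftl1 cKO.

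Haemoglobin transcripts, which are abundant in red blood cells, were few in neuronal nuclei, and their source there was not tested. Hbb-bs stood at 0.211 and 0.117 CPM in the control libraries (9 and 5 UMIs) and at 1.43 and 1.72 CPM in the libraries labelled Ftl1 cKO (57 and 85 UMIs). In barcodes of at most 100 UMIs it stood at 47.8 and 42.8 CPM against 95.1 and 68.2 CPM.

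Of the guide-related vector features, gRNA3long had 1 UMI, in Ftl1 cKO replicate 2, and gRNAslong had 2 UMIs, in control replicate 2, among the barcodes called as nuclei, so the guide of a nucleus could not be read. CreWpre was found in 67 and 458 barcodes of the control libraries and in 38 and 604 of the libraries labelled Ftl1 cKO.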
